A study of Rattus norvegicus with 12 samples.

How the data were processed

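RNA sequencing of polyadenylated RNA was analysed for 12 samples of rat intestine, 4 in each of 3 groups, with every sample in batch 1 per the labels. RNA was extracted with TRIzol and libraries were made with a VAHTS Universal kit, per the labels' protocols. Group membership and replicate numbers were taken from the sample titles. The group postSTC is labelled as postoperative, preSTC as preoperative, and preCTC as taken before a sham operation. The abbreviations STC and CTC are not explained in the labels and were not interpreted.

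The deposited count table holds whole read counts per gene, with 1 column per library and no pooling of replicates. The submitters' processing notes name fastp, HISAT2 and HTSeq and the rat assembly mRatBN7.2, without versions, settings or roles. The series' design text instead describes ileum, a TruSeq kit, Trimmomatic, hisat2 and featureCounts and a pig genome. The gene symbols and identifiers of the deposited table are those of rat, and that text was not used for the processing or for the tissue of any sample. Whether counting used strand, how reads with several matches were treated and whether duplicate reads were removed are not given in the sources used here. Members of multigene families with near-identical sequences, such as the Paneth cell defensins and some interferon-induced genes, are therefore uncertain as single genes. The second deposited table holds FPKM values, which the authors computed from the same counts. Within each gene, the FPKM values of the 12 libraries were proportional to the count divided by the column total, with a largest relative deviation of 7e-16. FPKM entered only alternative settings, because the counts carry the depth.

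The count table lists 18749 genes by symbol and NCBI Gene identifier, and 18531 identifiers (98.8%) matched a RefSeq gene table of assembly GRCr8. That table was used for names only. It is a different assembly from that of the counts, so no coordinates are given. All 12 value columns were matched to samples by title. Libraries held 30095656 to 39374682 counts. PCR reads without molecular identifiers are not independent molecules, so confidence intervals and floors of counts cover counting error only. Counts in replicates of the same group differed by more than sampling noise, with a chi-square per gene of at least 32.7 between any pair of replicates, so no library was treated as a duplicate.

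Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Library sizes were scaled by the trimmed mean of M values (TMM), and edgeR's filterByExpr on the group kept 15704 genes (83.8%). One quasi-likelihood model with the group as its only term was fitted to all 12 libraries, so that the 3 groups shared 1 estimate of the spread. The biological coefficient of variation was 0.322. The 3 comparisons were postSTC against preSTC, preSTC against preCTC and postSTC against preCTC. Each gene was tested with edgeR's two-sided quasi-likelihood F-test, p-values were adjusted by the method of Benjamini and Hochberg, and a gene was called changed at an adjusted p under 0.05. The standard error of a log2 fold change is the absolute log2 fold change divided by the square root of the F statistic. This definition replaced a standard error from voom, which was seen to be inflated for genes near 0 counts. Expression levels are CPM computed here with the TMM factors, given as mean ± SD over 4 libraries. Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts summed over that group. Where a group held 1 to 3 counts in all, the ratio is given with its 95% counting interval.

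A total of 39 gene lists for functions and cell types of the intestine was fixed before the data were examined, as were the tests, the named-gene rule and most alternative settings. The lists hold 750 genes, of which 739 are in the count table. Each list with at least 5 tested members was compared with all other genes by limma's camera on voom-transformed counts, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Beside it, camera with an estimated correlation and fry were run. No call of camera on the lists held with an estimated correlation (0 of 18, 0 of 19 and 0 of 19 in the 3 comparisons). At an unadjusted p under 0.05 that test gave 1, 5 and 5 lists, and fry gave 10, 21 and 18 after adjustment. The same method was applied to 2898 GO and KEGG terms of the deposited annotation with 15 to 300 tested genes, for postSTC against preSTC. The score of a list in a library is the mean of log2 CPM with a prior count of 2 over its tested genes, except for the colon-enriched scores used with the swap test, which are means of log2(CPM + 1). Counts of changed list members come from the gene test, adjusted over all genes and adjusted over the list alone. Genes were named by rule from those at an adjusted p under 0.05. For postSTC against preSTC, these were the 10 higher and 10 lower genes of largest change with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. For each of the other comparisons, 5 higher and 5 lower genes were taken. Members of each list with the smallest p were added. The rule named 74, 33 and 35 genes in the 3 comparisons. The text gives part of them, and any gene named outside the rule is said to have been chosen after its values were seen.

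Sample structure was described by principal components of log2 CPM with a prior count of 2, and by distances between libraries with an exact permutation test of the group labels over the 35 splits of 8 libraries. Whether replicate numbers pair postSTC with preSTC was checked on deviations from the group means. The correlations across genes of same-numbered libraries were 0.236, 0.158 and 0.168 for replicates 1, 5 and 7, each above the limit of 0.1 set for pairing. The numbers come from the sample titles, and the labels do not say what they mark. The blocked fit of all 12 libraries is therefore given beside results of that comparison where it changed a call or moved a count by over 1.5 times. That fit also ties preCTC libraries to the others by number, a pairing that was not taken to hold. The lists were tested with the block only in that fit. A blocked fit of the 8 libraries compared ended most calls of single genes and is given by its counts and for a few of them.

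Alternatives to the main choices were other scaling factors, other filters on low counts, DESeq2, limma voom, log2 of FPKM plus a pseudocount, a minimum fold, the 8 libraries compared alone, a replicate block, cell type scores as covariates, a baseline of both groups before surgery, and leaving out each library in turn. Robust shrinkage, leaving out seminal vesicle and prostate genes, and sample quality weights were added after the data were seen. Each library statistic, list score and named gene was screened for single libraries far from the others of their group with Dixon's ratio at a critical value of 0.829. For genes this was done on log2(CPM + 1), and gene groups under 3 counts were skipped, a scale chosen after a first screen gave degenerate values.

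The gene test was checked on counts simulated from the real means and library sizes, with 15570 genes tested and 50 genes changed at each of 4 fold sizes. For postSTC against preSTC it recovered 10% of the 1.5-fold changes, 52% of the 2-fold, 72% of the 3-fold and 80% of the 4-fold changes, with 5 false calls. For postSTC against preCTC the shares were 10%, 48%, 64% and 80%, with 5 false calls, and for preSTC against preCTC, simulated without change, there were 0 false calls. In a second simulation the cell cycle list, lowered 1.5-fold in postSTC, was called by camera with either correlation and by fry, and camera with the preset correlation falsely called 1 other list for postSTC against preSTC and 1 for preSTC against preCTC, and fry 1 for postSTC against preSTC.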

Results

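Polyadenylated RNA from 12 intestine samples of wild-type rats was sequenced in a series on how the small intestine adapts once the colon has been removed. The samples form 3 groups of 4. The group postSTC was taken after the operation, the group preSTC before it, and the group preCTC before a sham operation. Replicates 1, 2, 5 and 7 make up postSTC, and replicates 1, 5, 7 and 9 make up each of the other groups. No sample from after the sham operation was analysed here, so the operation and the time that passed cannot be separated. The labels do not say that replicates are separate animals, so p-values measure only the spread between these samples, which may be technical. The total count was 35411844, 37870799, 37816238 and 35769463 in preSTC1, preSTC5, preSTC7 and preSTC9. It was 34217255, 36103624, 36470458 and 36201005 in preCTC1, preCTC5, preCTC7 and preCTC9, and 30095656, 37684927, 34190595 and 39374682 in postSTC1, postSTC2, postSTC5 and postSTC7. Of 18749 genes in the count table, 15704 were tested.

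In postSTC7, 44.8% of all counts (Wilson 95% interval 44.80 to 44.83%) came from 16 genes of the seminal vesicle and prostate, a list made after these genes were seen to lead the counts of that library. Semg1, the gene of a major seminal clotting protein, alone took 17.1% (Wilson 95% interval 17.05 to 17.07%). In postSTC1, postSTC2, postSTC5 and preSTC7 the 16 genes took 0.0253, 0.0183, 0.0217 and 0.0203% of the counts. The Wilson 95% intervals of these shares were 0.0247 to 0.0259, 0.0179 to 0.0188, 0.0212 to 0.0222 and 0.0198 to 0.0208%. The remaining 7 libraries held 1 to 11 such counts each. The correlation of log2 CPM between replicates was 0.968 to 0.98 in preSTC, 0.958 to 0.978 in preCTC and 0.907 to 0.973 in postSTC. The first principal component held 45.9% of the variance and placed postSTC between preSTC and preCTC. The second held 18.5% and set postSTC7 at 116, with the other libraries between -34.2 and 28.3. Libraries of different groups lay farther apart than libraries of the same group in each pair of groups. The mean distances were 1.06 against 0.781 for postSTC and preSTC, 1.36 against 0.662 for preSTC and preCTC, and 1.22 against 0.812 for postSTC and preCTC. The one-sided exact permutation p was 0.0286 in each case, the smallest that 35 splits can give.

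**Figure D1:**
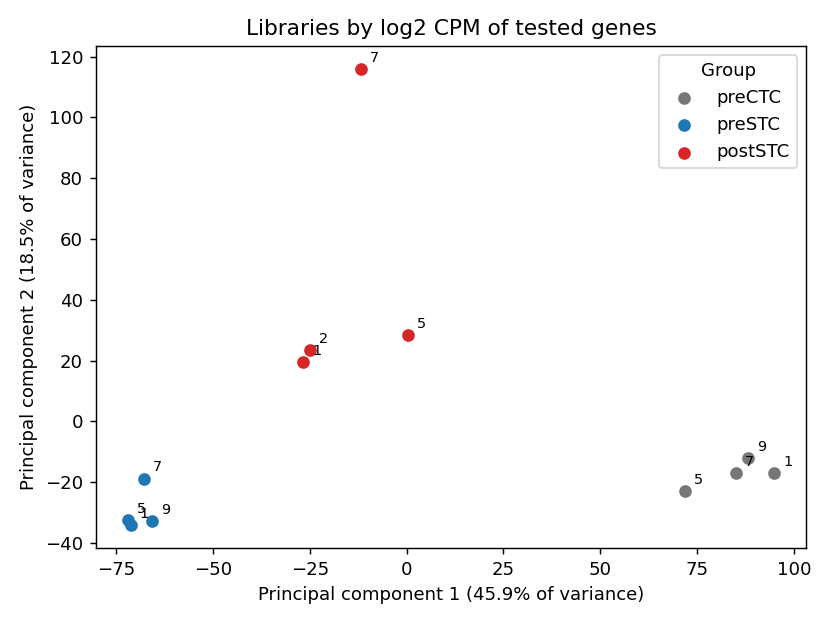
Each point is 1 library, placed by its first (horizontal) and second (vertical) principal component of log2 CPM over all tested genes, coloured by group and marked with its replicate number. The postSTC libraries lie between preSTC and preCTC on the first component, which held 45.9% of the variance, and postSTC7 stands at 116 on the second.

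The comparison of postSTC against preSTC asked how the intestine after the operation differed from the intestine before it. Of 28 cell cycle genes, 27 fell after the operation (adjusted p = 0.236 for the list with an estimated correlation). Top2a, which untangles replicated chromosomes, fell from 216 ± 15.3 CPM in preSTC to 94.3 ± 17.2 CPM in postSTC (SD, n = 4), a log2 fold change of -1.20 ± 0.13 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000605). The secreted antibacterial lectin gene Reg3b fell from 16730 ± 2195 to 2475 ± 787 CPM, and the ileal bile acid transporter gene Slc10a2 from 551 ± 23.9 to 205 ± 53.4 CPM (SD, n = 4, edgeR adjusted p = 0.000268 and 0.00387). Of 17 colon-enriched genes, 13 rose (adjusted p = 0.501 for the list with an estimated correlation). The homeobox gene Hoxb13, a marker of the distal bowel, rose from 0.198 ± 0.123 to 80.6 ± 35.9 CPM (SD, n = 4, edgeR adjusted p = 0.00254). Of 18 smooth muscle genes 9 rose, and of 22 fibroblast and matrix genes 9 rose, or 4 with the replicate block (adjusted p = 0.501 for both lists with an estimated correlation).

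In all, 2833 genes (18% of those tested) changed in postSTC against preSTC, 1749 higher and 1084 lower, at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 985 rose and 214 fell by at least 2-fold. The CPM of the groups' libraries did not overlap for 3464 genes (22.1% of those tested, where chance gives 2.86%). With the replicate number as a block, 1746 genes were called in the fit of all 12 libraries and 66 in a fit of the 8 libraries compared. Of the genes named by rule, 15 of 74 lost their call in the first of these fits and 61 of 73 in the second, so most single genes below were not called in the second fit. In the blocked fit of 8 libraries the adjusted p was 0.0694 for Top2a, postSTC against preSTC, 0.0707 for Reg3b, postSTC against preSTC, and 0.00179 for Hoxb13, postSTC against preSTC. With the smooth muscle score as a covariate 239 genes were called, and 54 of 74 named genes lost their call. That score was 6.98 to 7.61 in preSTC and 7.95 to 8.53 in postSTC, so as a covariate it also takes up part of the group difference. Leaving out preSTC1, preSTC5 or preSTC7 gave 1609, 1855 and 1681 genes. Without postSTC7, 2907 genes were called, 2325 of them shared with the full set and of the same direction.

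Among the gene lists that fell in postSTC against preSTC, the cell cycle list was the most uniform. Of its 28 tested genes, 27 fell, over all genes and adjusted over the list alone, with a median log2 fold change of -1.07 (camera adjusted p = 2.95e-27, and adjusted p = 0.236 with an estimated correlation). Mcm5, part of the helicase that opens DNA for replication, fell from 75.2 ± 8.79 to 32.6 ± 5.26 CPM (SD, n = 4, edgeR adjusted p = 0.000605). Without postSTC7, in which seminal transcripts took 44.8% of the counts, 27 genes of the list were again lower (camera adjusted p = 2.86e-25). Of 12 Paneth cell genes, 6 fell, and 7 fell and 1 rose adjusted over the list alone (median -1.55, camera adjusted p = 0.000113, and adjusted p = 0.501 with an estimated correlation). The Paneth cell defensin gene Defa9 fell from 2584 ± 635 to 696 ± 348 CPM (SD, n = 4, edgeR adjusted p = 0.0046), and Defa24 by 1.77 ± 0.36 on the log2 scale (SE, edgeR adjusted p = 0.00776). Defensin genes have near-identical copies, so their single values are uncertain. Of 17 genes of epithelial antimicrobial and oxidative defence, 5 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.00926, and adjusted p = 0.531 with an estimated correlation). Reg3g, a lectin gene close to Reg3b, fell by 2.53 ± 0.24 on the log2 scale (SE, edgeR adjusted p = 0.000316), and Nos2, the inducible nitric oxide synthase, from 58.7 ± 10.7 to 12.7 ± 6.98 CPM (SD, n = 4, edgeR adjusted p = 0.00252). Retnlb, a goblet cell gene also active against bacteria, rose from 0.141 ± 0.16 to 43.4 ± 28.7 CPM (SD, n = 4, edgeR adjusted p = 0.000605), and stood at 12.6 to 63.0 CPM in preCTC. For Retnlb, postSTC against preSTC gave a log2 fold change of 8.26, or 9.35 without preSTC1.

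Of 11 genes of bile acid transport and signalling, 3 fell in postSTC against preSTC, and 6 adjusted over the list alone (median -0.92, camera adjusted p = 0.000113, and adjusted p = 0.501 with an estimated correlation). Besides Slc10a2, the hormone gene Fgf19, which the ileum secretes in response to bile acids, fell from 9.77 ± 1.39 to 2.23 ± 1.46 CPM (SD, n = 4, edgeR adjusted p = 0.0076). Of 24 genes for digestion and uptake of carbohydrate and protein, 9 fell and 3 rose, and 11 fell and 5 rose adjusted over the list alone. The median log2 fold change of this list was -0.70, its mean was 0.47, and camera called it lower (adjusted p = 6.66e-05, and adjusted p = 0.531 with an estimated correlation). The list score was 7.9 in postSTC1, 5.92 to 6.71 in the other postSTC libraries and 6.51 to 6.86 in preSTC. The amino acid transporter genes Slc6a19 and Slc7a7 fell by 1.42 ± 0.20 and by 1.26 ± 0.23 on the log2 scale (SE, edgeR adjusted p = 0.00155 and 0.00491). The gene of lactase, Lct, was higher by 7.69 ± 1.89 (SE, edgeR adjusted p = 0.0173), with 243, 7.22, 0.56 and 0.67 CPM in postSTC1, postSTC2, postSTC5 and postSTC7. Its log2 fold change was 3.23 without postSTC1, its adjusted p was 0.0545, 0.0547 and 0.0527 without preSTC1, preSTC7 or preSTC9, and 0.226 with the replicate block. Of 22 genes of cholesterol synthesis, 2 fell, and 11 adjusted over the list alone (camera adjusted p = 3.19e-06, and adjusted p = 0.584 with an estimated correlation). Of 29 genes of oxidative phosphorylation, 1 fell, and 0 adjusted over the list alone, with a median log2 fold change of -0.22 (camera adjusted p = 0.000357, and adjusted p = 0.642 with an estimated correlation).

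A further 5 lists were called lower by camera in postSTC against preSTC with few changed members, and each lost its call when some single libraries were left out. Of 29 interferon response genes, 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.00558, and adjusted p = 0.642 with an estimated correlation, or 0.0576 without postSTC2). Tap1 and Psmb9, which serve the loading of peptides on MHC class I, fell by 1.06 ± 0.20 and by 0.93 ± 0.19 on the log2 scale (SE, edgeR adjusted p = 0.00486 and 0.00806), and some members of this list have near-identical copies. Of 22 T and NK cell genes, 0 changed in edgeR, where 5 were lower at an unadjusted p under 0.05, and DESeq2 called 4 lower and limma voom 2 (median -0.59, camera adjusted p = 0.00222, and adjusted p = 0.642 with an estimated correlation, or 0.119 without postSTC1). Of 16 goblet cell genes, 2 fell and 1 rose, also adjusted over the list alone, with a median of -0.43 and a mean of 0.12 (camera adjusted p = 0.034 for a lower level, and adjusted p = 0.642 with an estimated correlation). The goblet cell call was lost without postSTC5, postSTC7, preSTC1 or preSTC7 (adjusted p = 0.0951, 0.0791, 0.118 and 0.0564). Agr2, which helps mucins fold, fell from 1499 ± 329 to 811 ± 135 CPM (SD, n = 4, edgeR adjusted p = 0.0126). Of 22 enteroendocrine genes, 1 fell, also adjusted over the list alone (camera adjusted p = 0.0246, and adjusted p = 0.642 with an estimated correlation), and the call was lost without postSTC7, preSTC7 or preSTC9 (adjusted p = 0.269, 0.058 and 0.0646). That gene was Tac1, a tachykinin precursor, with a log2 fold change of -1.52 ± 0.37 (SE, edgeR adjusted p = 0.0168, or 0.054 without preSTC7). Of 10 erythrocyte genes, 0 changed in edgeR, where 2 were lower at an unadjusted p under 0.05, and DESeq2 called 1 lower and limma voom 0 (camera adjusted p = 0.0357, and adjusted p = 0.642 with an estimated correlation). The erythrocyte call was lost without postSTC1, postSTC7, preSTC5 or preSTC7 (adjusted p = 0.188, 0.114, 0.054 and 0.058).

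Of 17 tested colon-enriched genes, 13 rose in postSTC against preSTC, over all genes and adjusted over the list alone, with a median log2 fold change of 6.65 (camera adjusted p = 0.000431, and adjusted p = 0.501 with an estimated correlation). Hoxa13, a homeobox gene of the distal bowel, rose from 0.0472 ± 0.0236 to 13.4 ± 7.07 CPM (SD, n = 4, edgeR adjusted p = 3.34e-05). Atp12a, the colonic proton-potassium pump, rose from 0.536 ± 0.259 to 171 ± 103 CPM, and Scnn1b, a subunit of the epithelial sodium channel, from 0.397 ± 0.137 to 8.11 ± 1.46 CPM (SD, n = 4, edgeR adjusted p = 0.00347 and 0.000676). Without postSTC7, 14 of the 17 were higher (camera adjusted p = 0.000833). Of 18 smooth muscle genes, 9 rose, and 14 adjusted over the list alone (camera adjusted p = 1.9e-06, and adjusted p = 0.501 with an estimated correlation). Lmod1, which nucleates actin filaments in smooth muscle, rose from 51.1 ± 11.1 to 114 ± 25.3 CPM (SD, n = 4, edgeR adjusted p = 0.00327). Of 22 fibroblast and matrix genes, 9 rose, and 13 adjusted over the list alone (camera adjusted p = 2.22e-06, and adjusted p = 0.501 with an estimated correlation). Over all genes, 4 of them rose with the replicate block, and 13 without postSTC7. The matrix glycoprotein gene Thbs2 rose from 15.5 ± 2.34 to 58.8 ± 21.1 CPM, and Lox, which cross-links collagen, from 13 ± 1.34 to 32.5 ± 9.82 CPM (SD, n = 4, edgeR adjusted p = 0.00207 and 0.00244).

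Another 3 lists were called higher by camera in postSTC against preSTC, and these calls were lost with the replicate block and without some libraries. Of 12 tuft cell genes, 6 rose, also adjusted over the list alone (camera adjusted p = 0.00809, and adjusted p = 0.642 with an estimated correlation, 0.0846 with the replicate block or 0.0576 without postSTC2). With the block, 2 tuft cell genes rose. Dclk1, a kinase gene used as a tuft cell marker, rose from 20.4 ± 5.0 to 41.4 ± 11.2 CPM (SD, n = 4, edgeR adjusted p = 0.0144). Of 16 genes of blood and lymphatic endothelium, 5 rose, and 8 adjusted over the list alone, with 2 over all genes in the blocked fit and 8 without postSTC7 (camera adjusted p = 0.0213, and adjusted p = 0.642 with an estimated correlation). This call was lost with the block and without postSTC2 or postSTC5 (adjusted p = 0.143, 0.137 and 0.0701). Tek, an angiopoietin receptor, rose from 15.9 ± 0.713 to 40.7 ± 12.6 CPM (SD, n = 4, edgeR adjusted p = 0.00239). Of 18 circadian clock genes, 2 rose, also adjusted over the list alone (camera adjusted p = 0.0264, and adjusted p = 0.501 with an estimated correlation), and the call was lost with the block and without postSTC1 or postSTC2 (adjusted p = 0.0772, 0.0529 and 0.0576). Cry2, a repressor of the clock, rose by 1.10 ± 0.24 on the log2 scale (SE, edgeR adjusted p = 0.0107).

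**Figure D2:**
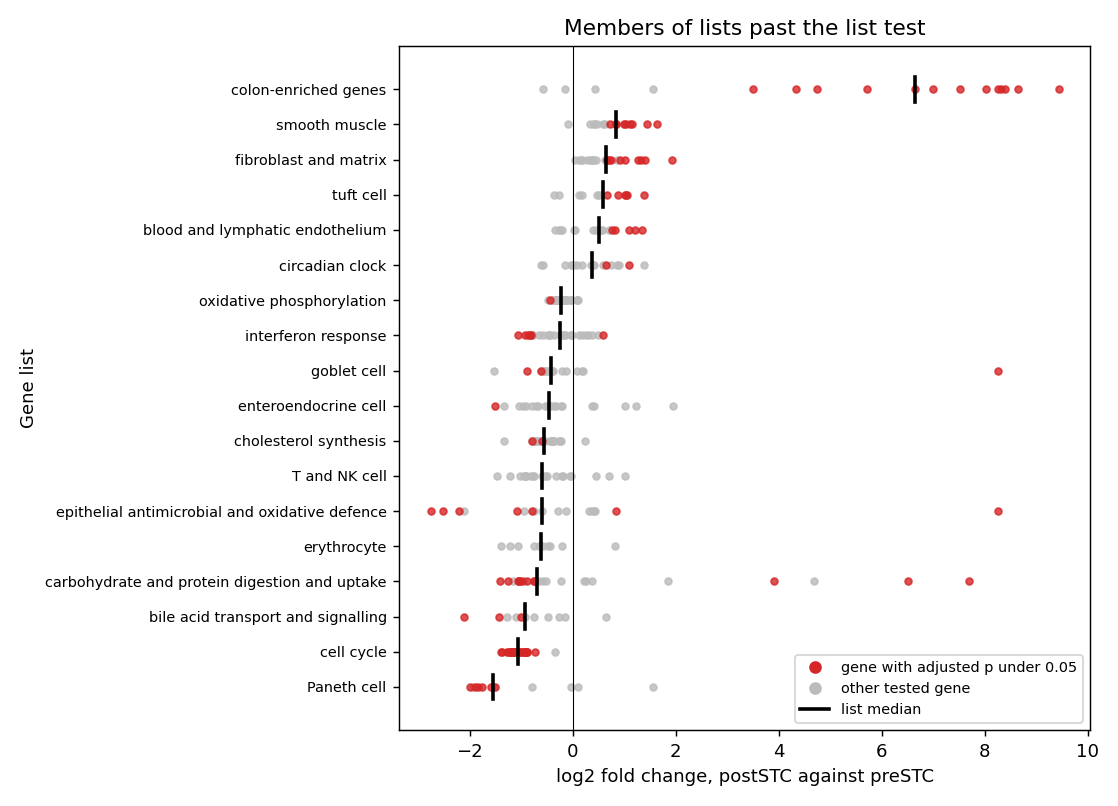
Each point is the log2 fold change (horizontal axis) of 1 tested gene in postSTC against preSTC, for the 18 lists past camera's test with a preset correlation (vertical axis). Red points had an edgeR adjusted p under 0.05, grey points did not, and the black bar is the list's median, from 6.65 for colon-enriched genes to -1.55 for Paneth cell genes.

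The other 21 lists did not pass camera's test in postSTC against preSTC, although single members changed in most of them. Of 21 genes of sodium and water absorption 7 rose (8 adjusted over the list alone), with members such as Scnn1b and Atp12a that also stand in the colon-enriched list. Of 11 genes of the proximal small intestine 4 rose (also adjusted over the list alone, camera adjusted p = 0.163, or 0.0436 with the replicate block, and adjusted p = 0.642 with an estimated correlation and no block). The score of this list was 7.87 in postSTC1, 5.56 to 6.2 in the other postSTC libraries and 5.16 to 5.28 in preSTC, so postSTC1 led the rise. Of 24 genes of fatty acid oxidation 5 rose (6 higher and 1 lower adjusted over the list alone), and of 21 lipid absorption genes 2 rose, also adjusted over the list alone. The lipid absorption score was 8.12 in postSTC1, 6.23 to 7.04 in the other postSTC libraries and 6.67 to 6.97 in preSTC. In xenobiotic metabolism 6 of 26 genes rose (8 adjusted over the list alone). Adh1, an alcohol dehydrogenase, rose from 21.6 ± 9.09 to 428 ± 243 CPM (SD, n = 4, edgeR adjusted p = 0.000633), and stood at 1090 to 2160 CPM in preCTC. Of 25 growth factor genes of the mucosa 7 rose and 2 fell, also adjusted over the list alone. Igf1, which drives tissue growth, rose from 33.6 ± 9.87 to 128 ± 69.4 CPM (SD, n = 4, edgeR adjusted p = 0.00667). Of 18 macrophage and dendritic cell genes 4 rose, also adjusted over the list alone. Clec7a, a receptor for fungal glucans, rose from 2.52 ± 0.606 to 20.9 ± 9.62 CPM (SD, n = 4, edgeR adjusted p = 0.000883). Of 11 neutrophil genes 4 rose, and 5 adjusted over the list alone. Cd177, a surface marker of neutrophils, rose by 3.47 ± 0.53 on the log2 scale (SE, edgeR adjusted p = 0.00218). It stood higher still in preCTC (126 to 440 CPM, beside 34.3 to 136 in postSTC), as did most colon-enriched genes by their means. Of 16 mast cell and eosinophil genes 4 rose, also adjusted over the list alone. Of 22 genes of inflammatory cytokines and NF-kB targets 2 rose and 2 fell, also adjusted over the list alone. Il33, an alarm cytokine, rose from 67.5 ± 13.2 to 211 ± 69.6 CPM (SD, n = 4, edgeR adjusted p = 0.00285). Of 17 crypt stem cell genes 4 fell (1 higher and 4 lower adjusted over the list alone). Cdca7, which is active in dividing cells, had a log2 fold change of -1.37 ± 0.22 (SE, edgeR adjusted p = 0.00255).

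Some of these lists passed camera's test with the preset correlation for postSTC against preSTC when 1 library was left out. Without postSTC7 this held for sodium and water absorption, xenobiotic metabolism, crypt stem cell, neutrophil and mast cell genes (adjusted p = 0.0335, 0.0102, 0.0434, 0.0334 and 0.0334), and for plasma cell genes and those of adipose tissue, mesothelium and pancreas (adjusted p = 0.0293 and 0.00469). With an estimated correlation these lists had camera adjusted p of 0.451 to 0.52 without postSTC7. For the other libraries left out, that test was not run. Without postSTC1 it held for lipid absorption, tight junction and macrophage genes (adjusted p = 0.0237, 0.0293 and 0.0135), and without postSTC5 for inflammatory genes (adjusted p = 0.0257). Without preSTC1 it held for fatty acid oxidation, inflammatory and B cell genes (adjusted p = 0.0197, 0.043 and 0.000129), and without preSTC7 for neutrophil genes (adjusted p = 0.0446).

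In the remaining lists of postSTC against preSTC, 3 of 13 chloride secretion genes rose and 1 fell, 1 of 18 tight junction genes rose and 2 fell, and 3 of 11 genes of adipose tissue, mesothelium and pancreas rose (3 and 1, 2 and 2, and 4 higher and 2 lower adjusted over the list alone). Of 22 immediate early and heat shock genes 2 rose and 1 fell, of 17 genes of serotonin and motility signalling 2 rose, and of 17 genes of microbial metabolite sensing 2 rose and 1 fell (2 and 1, 2, and 3 and 1 adjusted over the list alone). Tlr4, the receptor for bacterial lipopolysaccharide, rose from 8.52 ± 0.889 to 30.5 ± 15.7 CPM (SD, n = 4, edgeR adjusted p = 0.00293), and stood at 60.8 to 102 CPM in preCTC. Of 22 genes of enteric neurons and glia 1 rose, also adjusted over the list alone, and of 22 B cell and germinal centre genes 1 rose over all genes and 0 adjusted over the list alone. Of 11 plasma cell genes 0 changed in edgeR, where 1 was higher and 4 lower at an unadjusted p under 0.05, and DESeq2 called 2 lower and limma voom 1. Of 11 genes of MHC class II presentation 0 changed in edgeR, at an unadjusted p under 0.05, in DESeq2 or in limma voom. With the replicate block, the B cell and MHC class II lists were called lower by camera with the preset correlation (adjusted p = 0.0384 for both). Without the block, camera with an estimated correlation gave adjusted p = 0.758 and 0.697. Among these 39 lists, the median, the mean and camera's test differed in sign for digestion and uptake, goblet cell, lipid absorption, crypt stem cell, tight junction, plasma cell, neuron and glia, immediate early and microbial sensing genes.

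**Figure D3:**
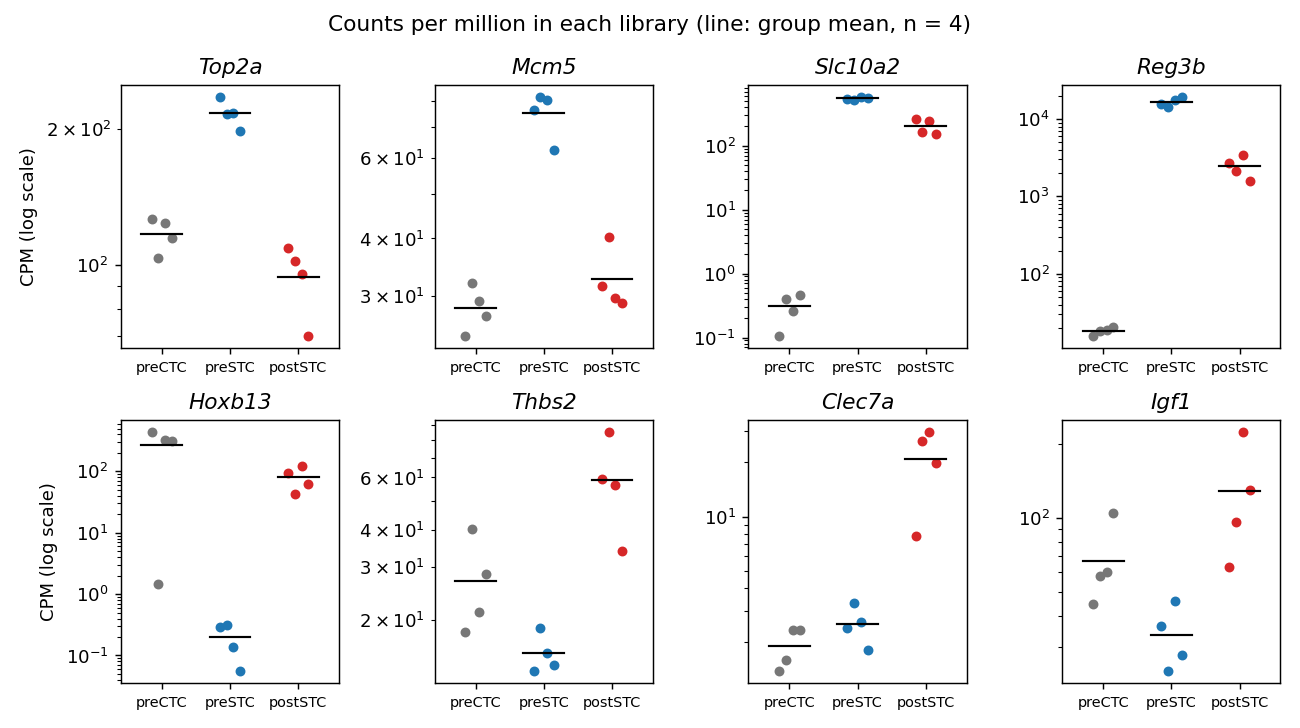
Each point is the CPM (logarithmic vertical axis) of 1 library for 8 genes, with the groups preCTC, preSTC and postSTC on the horizontal axis and a line at the group mean (n = 4). Top2a, Mcm5, Slc10a2 and Reg3b lie lower in postSTC than in preSTC, and Hoxb13, Thbs2, Clec7a and Igf1 lie higher.

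Several of the largest increases in postSTC against preSTC rested on postSTC7. Dnase2b, a deoxyribonuclease gene, was at 3040 CPM in postSTC7 and 0.532 to 0.776 CPM in the other postSTC libraries, and its log2 fold change of 12.4 ± 3.2 (SE, edgeR adjusted p = 0.0213) became 2.25 without that library (adjusted p = 0.171). For Dnase2b, postSTC against preSTC had an adjusted p of 0.0655, 0.0608 and 0.0615 without preSTC1, preSTC5 or preSTC9, and without preSTC7, which left 1 count in preSTC, a ratio of 56100 (95% counting interval 10100 to 2220000). For Cd52, postSTC against preSTC gave a log2 fold change of 8.33 ± 2.24 (SE, edgeR adjusted p = 0.0254), which was 0.53 without postSTC7 (adjusted p = 0.233). Cd52 is a surface glycoprotein gene of lymphocytes and of the male genital tract. The adjusted p of Cd52 was 0.32 with the replicate block and 0.0706, 0.0673, 0.0712 and 0.0701 without preSTC1, preSTC5, preSTC7 or preSTC9. The calcium channel gene Trpv6 had a log2 fold change of 9.52 ± 1.92 (SE, edgeR adjusted p = 0.00731), and of 4.99 without postSTC7 (adjusted p = 0.000691). The homeobox gene Hoxd13, another of the largest increases, rose from 0.0539 ± 0.0557 to 40.6 ± 18.9 CPM (SD, n = 4, edgeR adjusted p = 0.0021). For Hoxd13, postSTC against preSTC gave a log2 fold change of 9.44, and without preSTC5, which left 3 counts in preSTC, a ratio of 1460 (95% counting interval 498 to 7070).

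Among GO and KEGG terms, 300 of 2898 were called by camera in postSTC against preSTC, 69 higher and 231 lower, and 277 of them were called in the same direction without postSTC7. The term kinetochore had 52 of 109 genes lower and 3 higher (adjusted p = 1.66e-13, and adjusted p = 0.201 with an estimated correlation), and the KEGG pathway DNA replication 23 of 35 lower (adjusted p = 3.4e-13, and adjusted p = 0.346 with an estimated correlation). The proteasome pathway had 23 of 45 genes lower and the spliceosome pathway 45 of 132 lower and 2 higher (adjusted p = 5.21e-13 and 1.59e-12, and adjusted p = 0.348 and 0.222 with an estimated correlation). The collagen-containing extracellular matrix had 37 of 107 genes higher and 1 lower (adjusted p = 2.05e-06, and adjusted p = 0.482 with an estimated correlation).

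The groups preSTC and preCTC were both taken before any operation. Genes of gut position also parted them, with 7 of 7 tested Hox genes of groups 10 to 13 lower in preSTC. The comparison of preSTC against preCTC therefore cannot tell a difference between arms from one between segments of the intestine, for any list or gene below. The same limit holds for postSTC against preCTC. The ileal bile acid transporter gene Slc10a2 stood at 551 ± 23.9 CPM in preSTC and 0.306 ± 0.159 CPM in preCTC (SD, n = 4), a log2 fold change of 10.79 ± 0.39 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.4e-09). Of 24 digestion and uptake genes 18 were higher in preSTC, and of 17 colon-enriched genes 16 were lower (adjusted p = 0.277 and 0.317 for the lists with an estimated correlation). Hoxa13, a homeobox gene of the distal bowel, stood at 0.0472 ± 0.0236 CPM in preSTC and 53.5 ± 11.0 CPM in preCTC (SD, n = 4, edgeR adjusted p = 1.46e-07). The labels call the tissue intestine in all groups, and a design text that elsewhere describes pig names ileum.

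Between these groups 6077 genes (38.7%) changed in preSTC against preCTC, 2995 higher and 3082 lower, of which 1217 and 1609 by at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). On log2(FPKM + 1), which has no TMM scaling, 29.4% of the calls were higher in preSTC, against 49.3% here. The libraries of the 2 groups did not overlap for 7065 genes (45%, where chance gives 2.86%).

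Of 24 genes for digestion and uptake of carbohydrate and protein, 18 were higher in preSTC against preCTC and 19 adjusted over the list alone (median log2 fold change 4.10, camera adjusted p = 1.66e-13, and adjusted p = 0.277 with an estimated correlation). Slc6a19 had a log2 fold change of 9.82 ± 0.29 (SE, edgeR adjusted p = 6.12e-09), and Si, the sucrase-isomaltase of the brush border, was at 156 ± 64.9 CPM in preSTC and 0.1 ± 0.0795 CPM in preCTC (SD, n = 4, edgeR adjusted p = 1.38e-05). Of 21 lipid absorption genes 17 were higher (18 adjusted over the list alone, camera adjusted p = 3.01e-08, and adjusted p = 0.317 with an estimated correlation). Mttp, which loads lipid onto apolipoprotein B, stood at 570 ± 93.9 and 1.07 ± 0.328 CPM (SD, n = 4, edgeR adjusted p = 2.61e-07). Bile acid genes were higher in 9 and lower in 1 of 11, and 16 of 22 genes of cholesterol synthesis were higher (9 and 1, and 18, adjusted over the list alone). Both had a camera adjusted p of 1.56e-06, and adjusted p = 0.317 and 0.409 with an estimated correlation. Of 12 Paneth cell genes 10 were higher, also adjusted over the list alone (median 9.49, camera adjusted p = 7.37e-07, and adjusted p = 0.277 with an estimated correlation). Defa9, uncertain because of its near-identical copies, was higher by a log2 fold change of 9.48 ± 0.49 (SE, edgeR adjusted p = 1.46e-07). Of 28 cell cycle genes 25 were higher, and 27 adjusted over the list alone (median 0.96, camera adjusted p = 2.52e-13, and adjusted p = 0.277 with an estimated correlation). Mcm5 was higher by a log2 fold change of 1.42 ± 0.14 (SE, edgeR adjusted p = 1.57e-05). Of 17 genes of epithelial antimicrobial defence 7 were higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.0213, and adjusted p = 0.409 with an estimated correlation). Reg3g stood at 13390 ± 2294 and 14.7 ± 0.775 CPM (SD, n = 4, edgeR adjusted p = 7.26e-09). Of 22 enteroendocrine genes 5 were higher and 1 lower, also adjusted over the list alone. The neurotensin gene Nts stood at 61.7 ± 6.5 and 0.158 ± 0.0956 CPM (SD, n = 4, edgeR adjusted p = 1.42e-06). The enteroendocrine list had a camera adjusted p of 0.0316, and of 0.607 with an estimated correlation, and lost its call without preCTC1 or preCTC9 (adjusted p = 0.0666 and 0.0865).

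Among the lists of immune cells and responses, 5 were called higher by camera in preSTC against preCTC. The lists of macrophages, inflammatory cytokines, mast cells and neutrophils were not called (camera adjusted p = 0.422, 0.137, 0.361 and 0.399). Of 22 T and NK cell genes 17 were higher, also adjusted over the list alone (camera adjusted p = 1.15e-07, and adjusted p = 0.365 with an estimated correlation). Zap70, a kinase of the T cell receptor, was higher by a log2 fold change of 2.21 ± 0.30 (SE, edgeR adjusted p = 0.000173). Of 29 interferon response genes 18 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 3.6e-08, and adjusted p = 0.317 with an estimated correlation). Of 11 MHC class II genes 9 were higher, also adjusted over the list alone (camera adjusted p = 0.000108, and adjusted p = 0.365 with an estimated correlation). RT1-DMb, which helps load MHC class II, had a log2 fold change of 1.74 ± 0.22 (SE, edgeR adjusted p = 0.00011). Of 11 plasma cell genes 4 were higher, also adjusted over the list alone (camera adjusted p = 0.0194, and adjusted p = 0.277 with an estimated correlation). Prdm1, the regulator of plasma cell fate, stood at 68.2 ± 12.9 and 12.1 ± 3.52 CPM (SD, n = 4, edgeR adjusted p = 5.52e-05). Of 22 B cell genes 3 were higher and 1 lower (3 and 0 adjusted over the list alone, camera adjusted p = 0.0472, and adjusted p = 0.718 with an estimated correlation). The B cell call was lost without preCTC1, preCTC5, preCTC7, preSTC5 or preSTC7 (adjusted p = 0.0736, 0.175, 0.0557, 0.166 and 0.079).

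Of 17 colon-enriched genes, 16 were lower in preSTC against preCTC, also adjusted over the list alone (median -7.41, camera adjusted p = 0.000423, and adjusted p = 0.317 with an estimated correlation). Hoxb13 stood at 0.198 ± 0.123 CPM in preSTC and 273 ± 190 CPM in preCTC, and Tgm3, an epithelial transglutaminase, at 0.989 ± 0.432 and 1031 ± 710 CPM (SD, n = 4, edgeR adjusted p = 0.00024 and 0.000413). Within preCTC, preCTC5 was low for Hoxb13 (1.44 CPM, others 315 to 445), Atp12a (2.03, others 687 to 1130) and Tgm3 (5.12, others 1210 to 1640). Not all genes of the list were low there, with Car1 at 3108 CPM (others 226 to 494) and Hoxa13 at 60.1 CPM (others 40.6 to 64.7). Of 22 fibroblast and matrix genes 21 were lower, also adjusted over the list alone (camera adjusted p = 3.26e-11, and adjusted p = 0.277 with an estimated correlation). The collagen gene Col5a1 stood at 60 ± 6.25 and 165 ± 15.9 CPM (SD, n = 4, edgeR adjusted p = 5.71e-06). Of 18 smooth muscle genes 14 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 2.33e-06, and adjusted p = 0.409 with an estimated correlation). Cnn1, an actin-binding regulator of contraction, stood at 261 ± 60.5 and 1018 ± 320 CPM (SD, n = 4, edgeR adjusted p = 0.000102). Of 22 genes of enteric neurons and glia 8 were lower and of 16 endothelial genes 5 were lower, both also adjusted over the list alone (camera adjusted p = 0.00467 and 0.0166, and adjusted p = 0.442 and 0.591 with an estimated correlation). Of 10 erythrocyte genes 1 was lower, and 0 adjusted over the list alone (camera adjusted p = 0.0485, and adjusted p = 0.587 with an estimated correlation), and the call was lost without preCTC1, preCTC5 or preSTC9 (adjusted p = 0.0603, 0.119 and 0.114). The median, mean and test differed in sign for crypt stem cell, goblet cell and tight junction genes. C9, a complement gene, had 0 counts in preCTC and was at least 436-fold higher in preSTC, where it stood at 8.40 ± 4.78 CPM (SD, n = 4, edgeR adjusted p = 0.000344).

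The comparison of postSTC against preCTC set the samples after the operation beside the other arm before its sham operation. The ileal bile acid transporter gene Slc10a2 was at 205 ± 53.4 CPM in postSTC and 0.306 ± 0.159 CPM in preCTC (SD, n = 4), a log2 fold change of 9.36 ± 0.37 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.35e-08). The collagen gene Col5a1 was lower than in preCTC, at 72.2 ± 10.3 and 165 ± 15.9 CPM (SD, n = 4, edgeR adjusted p = 5.85e-05). Of 17 colon-enriched genes 5 were lower and 0 higher (6 lower and 1 higher adjusted over the list alone), and the list did not pass camera's test (median -1.44, adjusted p = 0.111). With the preset correlation it was called lower without preCTC5, the library low in Hoxb13, and without postSTC5 (camera adjusted p = 3.01e-05 and 0.049). With all libraries and an estimated correlation the camera adjusted p of the colon-enriched list was 0.667. Of 28 cell cycle genes 1 was lower, and 0 adjusted over the list alone (median -0.19, camera adjusted p = 0.0718). The cell cycle list was called lower by camera with the preset correlation without postSTC1, postSTC2 or preCTC9 (adjusted p = 0.00827, 0.0167 and 0.0401). With all libraries and an estimated correlation its camera adjusted p was 0.738.

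In total 2612 genes (16.6%) changed in postSTC against preCTC, 1455 higher and 1157 lower, of which 879 and 486 by at least 2-fold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment). On log2(FPKM + 1), 27.1% of the calls were higher, against 55.7% here. The libraries did not overlap for 2848 genes (18.1%, where chance gives 2.86%).

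Of 24 digestion and uptake genes 21 were higher in postSTC against preCTC and 22 adjusted over the list alone (median 5.41, camera adjusted p = 3.21e-18, and adjusted p = 0.275 with an estimated correlation). Of 21 lipid absorption genes 18 were higher and 20 adjusted over the list alone (camera adjusted p = 1.39e-15, and adjusted p = 0.275 with an estimated correlation). Mttp stood at 369 ± 234 and 1.07 ± 0.328 CPM (SD, n = 4, edgeR adjusted p = 6.12e-07). Of 11 genes of the proximal small intestine 8 were higher (8 higher and 1 lower adjusted over the list alone), of 11 bile acid genes 8 were higher and 1 lower, and of 12 Paneth cell genes 10 were higher, both also adjusted over the list alone. Their camera adjusted p were 0.000266, 9.79e-07 and 1.62e-08, and adjusted p = 0.275, 0.296 and 0.275 with an estimated correlation. Rbp2, the retinol-binding protein of enterocytes, stood at 321 ± 287 and 4.48 ± 3.15 CPM (SD, n = 4, edgeR adjusted p = 0.000101), and its log2 fold change of 6.16 was 5.33 without postSTC1 and 6.77 without preCTC5. Of 26 xenobiotic genes 11 were higher and 1 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.000807, and adjusted p = 0.386 with an estimated correlation). Cyp1b1, a cytochrome P450, had a log2 fold change of 3.95 ± 0.38 (SE, edgeR adjusted p = 3.92e-05). Of 22 cholesterol synthesis genes 2 were higher, also adjusted over the list alone (camera adjusted p = 0.0298, and adjusted p = 0.738 with an estimated correlation, or 0.346, 0.188 and 0.0864 without postSTC1, preCTC1 or preCTC9). Of 17 genes of antimicrobial defence 5 were higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0345, and adjusted p = 0.491 with an estimated correlation, or 0.0551, 0.0665 and 0.0711 without postSTC1, preCTC1 or preCTC9). Reg3g was higher by a log2 fold change of 7.29 ± 0.30 (SE, edgeR adjusted p = 4.58e-08).

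Of the immune lists in postSTC against preCTC, 15 of 29 interferon response genes, 8 of 11 MHC class II genes, 8 of 22 T and NK cell genes and 6 of 16 mast cell and eosinophil genes were higher (18, 8, 14 and 9 adjusted over the list alone). Their camera adjusted p were 1.62e-08, 4.57e-05, 2.63e-07 and 0.00129, and adjusted p = 0.296, 0.296, 0.386 and 0.371 with an estimated correlation. Psmb9 had a log2 fold change of 1.30 ± 0.19, Cd96, a receptor of T and NK cells, of 2.54 ± 0.39, and Fcer1a, the IgE receptor subunit of mast cells, of 2.18 ± 0.44 (SE, edgeR adjusted p = 0.000912, 0.00113 and 0.00638). Of 12 tuft cell genes 4 were higher and 6 adjusted over the list alone (camera adjusted p = 0.00261, and adjusted p = 0.437 with an estimated correlation). Avil, an actin-binding gene, was higher by a log2 fold change of 1.22 ± 0.25 (SE, edgeR adjusted p = 0.00671).

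Of 22 fibroblast and matrix genes 11 were lower and 1 higher in postSTC against preCTC (13 and 1 adjusted over the list alone, camera adjusted p = 3.51e-08, and adjusted p = 0.296 with an estimated correlation). Of 18 smooth muscle genes 5 were lower and 1 higher (8 and 1 adjusted over the list alone). The smooth muscle list had a camera adjusted p of 0.0128, and of 0.667 with an estimated correlation, or 0.104 without preCTC5. Of 22 genes of enteric neurons and glia 5 were lower (11 adjusted over the list alone), of 10 erythrocyte genes 7 were lower, and of 17 genes of microbial metabolite sensing 7 were lower and 2 higher (7 lower, and 7 lower and 3 higher, adjusted over the list alone). Their camera adjusted p were 0.000116, 3.79e-05 and 0.0258, and adjusted p = 0.371, 0.296 and 0.296 with an estimated correlation. Slc16a1, a transporter of lactate and short-chain fatty acids, stood at 125 ± 46.2 CPM in postSTC and 328 ± 5.21 CPM in preCTC (SD, n = 4, edgeR adjusted p = 0.00272). Of 29 oxidative phosphorylation genes 2 were lower and 1 adjusted over the list alone (camera adjusted p = 0.000266, and adjusted p = 0.667 with an estimated correlation). The median, mean and test differed in sign for fatty acid oxidation, crypt stem cell, goblet cell, tight junction, growth factor and serotonin genes. Cyp2w1, a cytochrome P450 gene, was lower by a log2 fold change of -3.94 ± 0.32 (SE, edgeR adjusted p = 1.09e-05).

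The largest increases in postSTC against preCTC were those of seminal vesicle genes such as Semg1 and Svs4, whose counts were led by postSTC7. Semg1 had 0 counts in preCTC and was at least 2700000-fold higher in postSTC (edgeR adjusted p = 0.0383). For Semg1, postSTC against preCTC lost its call without preCTC1, preCTC5, preCTC7 or preCTC9 (adjusted p = 0.0797, 0.0677, 0.0756 and 0.0744). Svs4, with 1 count in preCTC, had a ratio of 6330000 (95% counting interval 1140000 to 2.5e+08, edgeR adjusted p = 0.0138, or 0.069 without preCTC9). Without postSTC7, Semg1 was at least 4040-fold higher and Svs4 had a ratio of 10100 (95% counting interval 1810 to 399000). The Semg1 counts left were traces of 2885, 2692 and 2779 in postSTC1, postSTC2 and postSTC5, beside 2969 in preSTC7. If these are reads carried over from postSTC7, leaving out that library does not remove its reads. The folds without it are then not independent of it.

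Genes that differed from both baselines were counted next. Of the 15704 genes, 224 changed the same way in postSTC against preSTC and in postSTC against preCTC, 164 higher and 60 lower. Independent lists of these sizes would share 162 higher and 79.9 lower genes. At an unadjusted p under 0.05, 803 genes changed the same way, where independent lists would share 833 and 20 simulations of unchanged groups, with 15555 genes tested, gave a mean of 173 through the shared postSTC libraries alone. The simulations drew all 3 groups from the same means, while preSTC and preCTC differed in 6077 genes. A difference between baselines also keeps the 2 comparisons from being independent. Neither the simulated mean nor the counts of independent lists are therefore a chance level here. A further 391 genes changed in opposite ways, 230 of them higher than preSTC and lower than preCTC. With the 4 postSTC libraries halved in the 6 possible ways, so that the comparisons shared none of them, 60 to 95 genes were higher in both and 17 to 28 lower, where independent lists would share 50.9 to 200 and 17.1 to 76.9. With postSTC1 and postSTC2 set against preSTC, 95 higher and 22 lower genes were shared, above the 50.9 and 17.1 of independent lists. In each other halving both counts lay below those of independent lists. The shared count was 282 without postSTC7 (206 higher and 76 lower, where independent lists would share 189 and 102), and 121 with the replicate block. It was 431 without postSTC1, and 134, 130, 139, 132 and 136 without preCTC1, preCTC7, preSTC1, preSTC7 or preSTC9.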

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

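The splits of the samples were planned before the results were seen, and the tests of the seminal, Hox, muscle, swap, colon share, carry-over and cell cycle explanations were chosen after the results they concern had been seen. Of 376 groups of 4 libraries screened, 30 held 1 library far from the other 3, where chance gives about 1 in 20 groups, or 19. In postSTC7 there were 16 such values.

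The seminal genes stood far above the other postSTC libraries in postSTC7, with 301000 CPM of Semg1 (others at most 93.3), 235000 of Svs4, 63100 of Svs3a, 55800 of Svs6 and 48400 of Svs5. The 16 seminal vesicle and prostate genes took 44.81% of its counts, its 10 leading genes 46.73% (others at most 4.734%), and its TMM factor was 0.5684 (others at least 1.028). In the same library Dnase2b stood at 3040 CPM, Cd52 at 3230, Pou3f3 at 43.5, Cldn8 at 127, Fcrl2 at 27.9 and Synpo2 at 256, all above the others, and Slc6a19 at 220 and C9 at 0.0896, below them. In preSTC7 the seminal genes took 0.0203% (others at most 3.11e-05%), Dnase2b stood at 0.513 CPM and Cd177 at 10.2 CPM, all above the others.

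Within preCTC, Hoxb13 stood at 1.44 CPM, Atp12a at 2.03 and Tgm3 at 5.12 in preCTC5, below the other 3 libraries, and Cox5b stood at 301 CPM in preCTC9 (others at least 381). The total of preCTC1 was 34.22 in units of 1e+06 counts, with the others from 36.1 to 36.47. In postSTC5 the score of inflammatory cytokine genes was 2.29 (others at most 1.7), Nos2 stood at 23.1 CPM and Hsd3b2 at 3.43 CPM, above the others. In preSTC1 the score of sodium and water absorption genes was 5.52 (others at most 5.12), Apoc2 stood at 141 CPM, above the others, and Cry2 at 9.87 CPM, below them.

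For the seminal transcripts, 16 of 16 listed genes stood at least 100 times above the highest of the 7 libraries without traces, which restates the observation, since the list was made from it, and leaves tissue or fluid of the seminal vesicle or prostate in the sample as an untested candidate source. Over the 9 genes with the most counts in postSTC7, the median trace relative to it was alike in postSTC1, postSTC2, postSTC5 and preSTC7, with a ratio of 1.16 between the highest and lowest library, as reads assigned between libraries in handling or sequencing would give. Single genes ranged from 230 to 464 trace counts per 1e+06 counts of postSTC7, with an SD of at most 0.28 on the log2 scale. Reads assigned that way would mean that all postSTC libraries and preSTC7 shared a step of handling. The other 7 libraries held 1 to 11 such counts each. Handling would then nearly follow the operation, although the labels give 1 batch for every sample. Its effect on the comparisons was not tested. No biological explanation was tested. Leaving out postSTC7 gave 2907 changed genes for postSTC against preSTC, and leaving out the seminal genes 2812, beside 2833.

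For the genes that parted preSTC from preCTC, the median log2 fold change of Hox groups 10 to 13 minus that of groups 1 to 8 was -9.74, with 7 of 7 genes of groups 10 to 13 lower in preSTC. Hox genes mark position along the gut, so samples from different segments of the intestine may account for the difference. Samples from 1 position would be alike in such genes. The 7 genes of groups 10 to 13, with a median of -9.29, therefore argue against a difference of animals alone as the source of their own difference. A larger share of muscle in preCTC would have lowered epithelial genes alike. The tight junction list had a median of 0.04 (median absolute deviation 0.59, 4 genes higher and 2 lower) beside 4.10 for digestion genes. This argues against muscle as the source of the difference in digestion genes, but not against a larger share of muscle in preCTC. Of 18 smooth muscle genes 14 were lower in preSTC and 1 higher, and of 22 fibroblast and matrix genes 21 were lower. No single sample stood out as swapped, with 0 of 4 preSTC libraries above the lowest colon-enriched score of preCTC (mean log2(CPM + 1)), but an exchange of the whole groups would give the same 0 and stays open. Whether the animals of the 2 arms also differed was not tested and stays open.

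For the colon-enriched genes of postSTC, reads assigned from preCTC libraries would give shares of colon counts of the size of the traces, and the lowest share in postSTC was 11.9%, beside 0.0464% for the highest trace. Colon tissue in the samples and expression of colon genes in the small intestine cannot be told apart, because 63.5% of held-out colon genes lay within 2-fold of the level from 1 share per library, between the limits set from 92.3%, the lowest of preCTC1, preCTC7 and preCTC9. The library preCTC5, low in Hoxb13, was left out of that reference after its values were seen and reached 30.8%, so the limits depend on that choice. Colon tissue like preCTC would not give genes above both baselines. For 168 genes every postSTC library stood above the other 8, where chance gives 31.7 with all 12 libraries taken as exchangeable. Colon tissue unlike preCTC could give such genes, so this count does not exclude colon tissue in the samples. Tissue like preCTC at these shares would give the cell cycle list a median log2 fold change of -0.14, beside the observed -1.07 (median absolute deviation 0.2). A change with the operation, with time, with handling or with other tissue in the samples stays open for the genes above both baselines and for the cell cycle list.

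Other splits of the 8 libraries tested the counts of changed genes and lists. For genes, 1 of 35 splits, the real one, gave as many in each comparison. The counts were 2833 in postSTC against preSTC (highest other 0), 6077 in preSTC against preCTC (highest other 0) and 2612 in postSTC against preCTC (highest other 52). A share of 1 of 35 is the smallest that these splits can give, with no correction for 3 comparisons, so chance is unlikely but not excluded. For gene lists, 9, 9 and 6 of 35 splits gave as many as the real 18, 19 and 19 lists (highest others 20, 23 and 23), and for annotation terms 3 of 35 gave as many as the real 300 (highest other 372), so chance is not excluded for the number of lists and terms. Among the 8 splits that part all 3 pairs of replicate numbers of postSTC and preSTC, the 7 others gave at most 0 genes, 18 lists and 341 terms. The smallest share that these splits allow is 1 of 8, above the limit of 0.05, so with the numbers taken as pairs they cannot exclude chance for that comparison. For genes changed the same way against both baselines, 1 of 100 relabelings of the 12 libraries, the real one, gave as many (224, highest other 0). In 99 of the 99 others at least 1 comparison called 0 genes, since relabeling mixes 2 baselines that differ in 6077 genes, so a shared count of 0 was fixed and this test says nothing about chance.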

How the results depend on the processing

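Robust shrinkage, leaving out seminal genes and sample quality weights were chosen after the data were seen, and the other alternatives before. Of the counts of changed genes, 2833 in postSTC against preSTC stayed within 1.5 times under other scaling factors, other filters, DESeq2 (3865), limma voom (2391), the 8 libraries alone (1928), the B cell score (2548), robust shrinkage (2837), without seminal genes (2812) and with quality weights (4220). It was 1199 with at least 2-fold change, 521, 653 and 310 with FPKM (pseudocounts of 1 and 0.1, and 1 over all genes), 239 with the smooth muscle score as a covariate and 1241 against both groups before surgery. For preSTC against preCTC, 6077 became 2826 with at least 2-fold change, 3824, 3753 and 3695 with FPKM and 1500 with the smooth muscle score. For postSTC against preCTC, 2612 became 1365 with at least 2-fold change, 1455 with the 8 libraries alone and 1668, 1569 and 1555 with FPKM. The minimum fold lowers counts by construction. The smooth muscle score was lower in every preSTC library than in all others, so as a covariate it takes up part of the difference from preSTC. Otherwise the cause was not tested.

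With FPKM, the median log2 fold change of all genes moved to -0.10 and -0.16 for preSTC against preCTC with pseudocounts of 1 and 0.1, and to -0.17, -0.24 and -0.11 for postSTC against preCTC in the 3 FPKM settings. In preSTC against preCTC 29.4, 29.9 and 28.4% of calls were higher with FPKM, and in postSTC against preCTC 27.1, 31.4 and 26%.

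With the replicate number as a block, postSTC against preSTC gave 1746 genes in all 12 libraries, 1620 of them shared with the fit without it, and 66 in the 8 libraries compared, and postSTC against preCTC 1399 and 151. For preSTC against preCTC the block gave 5729 and 7035 genes. The numbers were not taken to pair the arms, because 1 of the 4 correlations of same-numbered libraries was under the limit of 0.1, with 0.222, -0.028, 0.171 and 0.145 between preSTC and preCTC (mean 0.141, exact p 0.0833 over 24 matchings, highest other 0.187), and not every sample correlated best with its own number. Between postSTC and preCTC they were 0.22, -0.016 and 0.054. In the fit of 12 libraries the block ended the calls of 15 of 74 named genes in postSTC against preSTC, and in the fit of 8 libraries those of 61 of 73. Among the lists of that comparison it ended the tuft cell, endothelium and circadian calls, brought in the MHC class II, B cell and proximal small intestine calls, and changed no other call.

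The count of genes changed against both baselines, 224, was 418 with DESeq2, 121 with the replicate block and 507 with quality weights, and the cause was not tested. Camera with an estimated correlation called 0 lists in each comparison (1, 5 and 5 at an unadjusted p under 0.05) and 0 terms, and fry called 10, 21 and 18 lists. Leaving out 1 library gave 1609 to 3684 genes in postSTC against preSTC, 5037 to 5460 in preSTC against preCTC, 1780 to 3123 in postSTC against preCTC, and 130 to 431 against both baselines. It gave 14 to 22, 16 to 21 and 17 to 23 lists in the 3 comparisons, and 248 to 391 terms. The exact test of distances kept its p of 0.0286 with the 1000 most variable genes.

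In postSTC against preSTC, 54 of 74 named genes lost their call with the smooth muscle score, and 38, 33 and 48 in the 3 FPKM settings. With the smooth muscle score, the log2 fold change of Dnase2b, postSTC against preSTC, turned to -5.56 and that of Cldn8 to -0.09. Within postSTC, postSTC7 was highest in both genes and in that score (8.53), and the cause of the turns was not tested. Against both groups before surgery 16 named genes turned, because preCTC enters that baseline, with Reg3b at 2.16, Reg3g 2.38, C9 3.08, Plg 0.05, Defal1 2.69, Fgf19 2.86, Defa6 2.96, Defa9 2.85, Defa24 3.28, Slc10a2 3.96, Slc6a19 3.48, Slc7a7 1.32, Tac1 0.17, Tap1 0.13, Psmb9 0.19 and Pigr -0.11. Over all alternatives, named genes kept direction and call in 1486, 761 and 771 cases, lost the call in 412, 64 and 94 and turned in 18, 0 and 0 (postSTC against preSTC, preSTC against preCTC, postSTC against preCTC). In simulated counts at these depths, the test found 10% of 1.5-fold and 52% of 2-fold changes in postSTC against preSTC, so small changes can be missed.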

Other observations

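The genes of this part were chosen after their values were seen, and the test of the macrophage genes was written before those genes were looked at. With postSTC7 left out, 206 genes were higher in postSTC than in both groups before surgery, and several of them are known from macrophages that take up lipid or fuse. Spp1, the gene of osteopontin, stood at 165 ± 108 CPM in postSTC, 2.49 ± 1.11 in preSTC and 0.967 ± 0.478 in preCTC (SD, n = 4). The matrix protease gene Mmp12 stood at 114 ± 73.9, 3.87 ± 0.891 and 2.51 ± 1.28 CPM, and Gpnmb, a membrane glycoprotein gene, at 298 ± 213, 15.6 ± 5.32 and 22.7 ± 8.22 CPM. All 3 were higher in 4 of 4 postSTC libraries than in the other 8. Their log2 fold changes without postSTC7 were 6.36, 5.15 and 4.55 for postSTC against preSTC (edgeR adjusted p = 7.93e-05, 0.000187 and 0.000348) and 7.73, 5.78 and 4.01 for postSTC against preCTC (edgeR adjusted p = 1.07e-06, 1.02e-05 and 0.000121). Sfrp4, a secreted inhibitor of Wnt signalling, was higher by 6.10 and 4.01 in these fits (edgeR adjusted p = 0.000348 and 0.000429). Fut2, which adds fucose to mucosal glycans, had log2 fold changes of -0.76 and -0.75 (edgeR adjusted p = 0.0229 and 0.0218).

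More lipid-loaded or fused macrophages in postSTC may account for Spp1, Mmp12 and Gpnmb. Of 11 other tested genes of such macrophages, 5 rose in postSTC against preSTC, with a median log2 fold change of 0.99, just under the value of 1 set beforehand, so the test left the hypothesis undecided. Ctsk, Trem2 and Apoe rose by 4.41, 3.56 and 2.48 (edgeR adjusted p = 0.000855, 0.00128 and 0.0043), and Lgals3 and Fabp5 had log2 fold changes of 0.02 and 0.03 (edgeR adjusted p = 0.963 and 0.949). Lpl, one of the 11, is also abundant in fat, and the median was 0.79 without it. Without postSTC7 the median of the 11 was 0.86, and for postSTC against preCTC it was 1.35 with 6 genes higher. Cd9, 1 of the 5 that rose against preSTC, was lower in postSTC than in preCTC (log2 fold change -1.16, edgeR adjusted p = 0.00345). The general macrophage and dendritic cell list, which shares Itgax with these genes, had a median of 0.01 for postSTC against preSTC. The epithelium also expresses some of these genes, and Lgals3 stood at 678 to 860 CPM in the preSTC libraries.

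Genes of fat cells were also higher than both baselines without postSTC7. Fabp4 stood at 334, 396, 973 and 30.1 CPM in postSTC1, postSTC2, postSTC5 and postSTC7, and Lep, the leptin gene, at 66.6, 71.2, 187 and 0.31 CPM. Without postSTC7, 6 of 12 genes of adipose tissue, mesothelium and pancreas were higher in postSTC against preSTC (camera adjusted p = 0.00469, and adjusted p = 0.451 with an estimated correlation) and 4 of 12 in postSTC against preCTC (camera adjusted p = 0.0257, and adjusted p = 0.566 with an estimated correlation). With all libraries 3 and 1 of 11 genes were higher (camera adjusted p = 0.427 and 0.692, and adjusted p = 0.758 and 0.898 with an estimated correlation). The score of this list was 4.4, 4.24, 5.43 and 1.76 in postSTC1, postSTC2, postSTC5 and postSTC7. Single libraries before surgery reached scores close to those of postSTC1 and postSTC2, with 4.33 in preSTC7 and 4.36 in preCTC9. More fat tissue in postSTC5, and less clearly in postSTC1 and postSTC2, may account for part of the genes higher than both baselines. Whether fat tissue also brought the macrophage genes was not tested. In postSTC7, where Fabp4 was lowest, Spp1, Mmp12 and Gpnmb stood at 39.1, 39.5 and 84.7 CPM.

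Hoxc8, a homeobox gene of intermediate position along the body, stood at 8.54 CPM in postSTC, 8.68 CPM in preSTC and 0.006 CPM in preCTC. Apoa4, an apolipoprotein gene of the small intestine, stood at 2966 CPM in postSTC1 and 149, 91.2 and 186 CPM in postSTC2, postSTC5 and postSTC7. The scores of the colon-enriched list, as means of log2(CPM + 1), were 4.67, 3.99, 5.28 and 4.06 in postSTC1, postSTC2, postSTC5 and postSTC7, 6.11, 3.76, 5.59 and 5.62 in preCTC1, preCTC5, preCTC7 and preCTC9, and 1.42, 1.65, 1.31 and 1.43 in preSTC1, preSTC5, preSTC7 and preSTC9.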
